A study of Caenorhabditis elegans with 12 samples.

How the data were processed

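The study sequenced polyadenylated RNA from whole animals of 4 strains of Caenorhabditis elegans: N2, CA-CRTC-1, CA-AAK-2 and the double strain CA-AAK-2;CA-CRTC-1. Each group has 3 samples, which the series describes as biological replicates, and all 12 samples were used. Synchronised animals were grown at 20 degrees and collected at the L4 stage. Libraries were made from 4 micrograms of total RNA with an integrity number of 10, with a kit that does not keep the strand, and sequenced in 50 cycles from both ends.

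The deposited values are CPM, which the authors normalised with edgeR for depth and RNA composition across all samples. Per the submitters' processing notes, base calls came from CASAVA 1.8.2, reads were trimmed with cutadapt and aligned with TopHat2 2.0.8, and genes were counted with HTSeq; the notes say that genes under 1 CPM were discarded, yet 743 of the deposited genes have a mean under 1 CPM, so how that filter was applied is not known. The series text names both ce6 and WS238, so the exact genome build is uncertain. Coordinates here come from WBcel235 and were used only to place genes and their neighbours. Each of the 4 tables has 14508 entries, of which 72 carry a retired identifier, and 3 repeated names were merged, leaving 14505 genes, 13820 of them with a symbol.

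Dividing each column by its smallest step gave whole numbers for 100% of values within 0.02 reads, so the counted reads could be recovered. Their number was 30887631 to 48989013 per library and the columns sum to 862226 to 902133 CPM. 1 read equals 0.0178 to 0.0285 CPM. A group with 0 reads was placed under a floor of 3 reads over its libraries. This floor covers counting error only, whereas the SE and SD given with ± come from the spread among libraries.

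Differences were tested with limma 3.58.1 in R 4.3.3 on log2 of CPM plus 0.5, with a trended prior, all 12 samples in 1 fit and no term for replicate number. Genes needed a mean of at least 1 CPM over all samples and 5 CPM over the 6 samples compared. Calls required a Benjamini-Hochberg adjusted p of at most 0.01 and a change of at least 1.5-fold. The 5 pairwise comparisons and the interaction, which is the CA-CRTC-1 difference with CA-AAK-2 minus that without it, used the same thresholds, which follow the series text. Tests, filters, comparisons, gene lists and alternatives were chosen before the data were examined, except where the text says otherwise.

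Replicate numbers are given in the labels, which do not say what a number shares. The deviations of same-numbered samples from their group means correlated at 0.252, 0.313 and 0.275 between the CA-AAK-2 and double strains, against -0.259 to -0.0233 for samples with different numbers. By the rule that all 3 pairs exceed 0.1 the numbers were taken to pair the samples of these 2 strains. The pairing comes from the data and not from the design. It may have arisen by chance, since N2 replicate 1 and CA-CRTC-1 replicate 2, with different numbers, correlated at 0.334. The other comparisons of 2 strains did not meet the rule.

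The 39 gene lists cover the AMPK and CRTC-1 pathway with the transgenes, metabolism, stress responses, defence, cuticle and moulting, germ cells, neurons, muscle, intestine, pharynx, ribosomes, proteasome, autophagy and histones. A list of mitochondrially encoded genes had 0 members in the tables and was not analysed here. The other 38 were tested in the 6 contrasts, 228 tests in all, with camera at a preset correlation of 0.01, at least 4 measured members and Benjamini-Hochberg adjustment over the lists of a contrast, called at 0.05. camera compares a list with all other genes tested. The same tests were repeated with a correlation estimated from the data and with fry, which asks whether a list's genes move 1 way on balance.

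The genes named were fixed by rule. They are 16 genes in every comparison; the 8 largest rises and 8 largest falls of a pairwise comparison (5 and 5 for the interaction) among called genes with a name of the form abc-1 and no overlap between groups; and up to 4 called members, by adjusted p, of each list that camera called or that had 3 or more called members. The text uses part of the genes the rule gives, leaving out most whose call depends on 1 library.

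The effect of each transgene in both backgrounds was compared by Pearson and Spearman correlation across genes. Overlaps between strains against N2 were set beside independent lists and 20 simulations of unchanged groups. These were drawn around the N2 means and shared their drawn N2 libraries. Alternatives were pseudocounts of 0.1 and 2, a comparison filter of 1 CPM, no filter, rescaling by the median ratio or to equal totals, a fit of only the groups compared, a constant prior, replicate number as a block, an adjusted p of 0.05 without a fold threshold, edgeR 4.0.16 on the recovered reads, and leaving out each library in turn. Leaving out each library for the gene lists was chosen after seeing the data. Other splits of the samples were counted with the same test.

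On simulated data of 13762 genes with added changes, limma recovered 93.9 to 97.0% of 4-fold, 89.6 to 97.0% of 2-fold and 38.8 to 50.7% of 1.5-fold changes, and called at most 3 unchanged genes per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.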

Results

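RNA was sequenced from whole Caenorhabditis elegans at the L4 larval stage in 4 strains with 3 libraries each, 12 libraries in all. N2 was the wild type. The CA-CRTC-1 strain carried a form of CRTC-1, the CREB-regulated transcriptional coactivator, with the changes S76A and S179A. The CA-AAK-2 strain carried an active form of AAK-2, a catalytic subunit of AMP-activated protein kinase, which senses low cellular energy and phosphorylates CRTC-1. The CA-AAK-2;CA-CRTC-1 strain carried both and is called the double strain here. The design therefore asks what each transgene changes and whether CA-CRTC-1 acts in the same way with and without CA-AAK-2. The deposited values are CPM (counts scaled to a common library size), normalised by the authors with edgeR for depth and RNA composition, for 14505 genes. They trace back to 30887631 to 48989013 counted reads per library, so that 1 read stands for 0.0178 to 0.0285 CPM, and the 10 most abundant genes took 4.60 to 5.38% of the reads.

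A gene was called when limma gave a Benjamini-Hochberg adjusted p of at most 0.01 and a change of at least 1.5-fold, among genes with a mean of at least 5 CPM over the libraries compared. Differences are log2 fold changes ± SE, and levels are mean CPM ± SD with n = 3. Gene lists were tested with camera, which compares the mean test statistic of a list's members with that of all other tested genes. For each list the counts adjusted over the list alone equalled those over all genes unless a second pair is printed. The kit keeps no strand, and members of near-identical families (small heat shock, major sperm protein, vitellogenin and collagen genes) and overlapping genes share reads, so single members of these families are less certain than the family.

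The transgenes were plain in the reads. aak-2 (WBGene00020142) lies on chromosome X at 16796087 to 16803398, crtc-1 (WBGene00021237) on chromosome I at 2026316 to 2033748 and praf-3 (WBGene00017070), drawn beside them because of its fall with CA-CRTC-1, on chromosome IV at 8379983 to 8381947 in WBcel235. aak-2 lay at 61.7 ± 5.58 CPM in N2 and at 2530 ± 102 CPM in the CA-AAK-2 strain, a difference of 5.35 ± 0.08, and at 2992 ± 250 CPM in the double strain. crtc-1 rose from 20.5 ± 2.62 CPM in N2 to 189 ± 16 CPM in the CA-CRTC-1 strain (3.18 ± 0.10). In the double strain crtc-1 reached 362 ± 15.6 CPM, which was 0.94 ± 0.10 above the CA-CRTC-1 strain, and its increase over the matching strain without the transgene was 2.03 times as large. Reads do not separate transgene from endogenous transcripts. rol-6, a cuticle collagen whose mutant form is a common transformation marker, was higher than in N2 (175 ± 9.0 CPM) in all 3 transgenic strains, at 410 ± 15.2, 337 ± 14.2 and 605 ± 167 CPM in the CA-CRTC-1, CA-AAK-2 and double strains. Several other cuticle genes rose too, and the source of the added rol-6 reads was not tested. crh-1, the worm CREB gene, did not pass the threshold in any comparison; it was 0.52 ± 0.11 above N2 in the CA-CRTC-1 strain and passed without CA-CRTC-1 replicate 2 (0.60) or N2 replicate 3 (0.61), and it was 0.51 ± 0.11 above N2 in the double strain and passed without N2 replicate 3 (0.60).

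**Figure D1:**
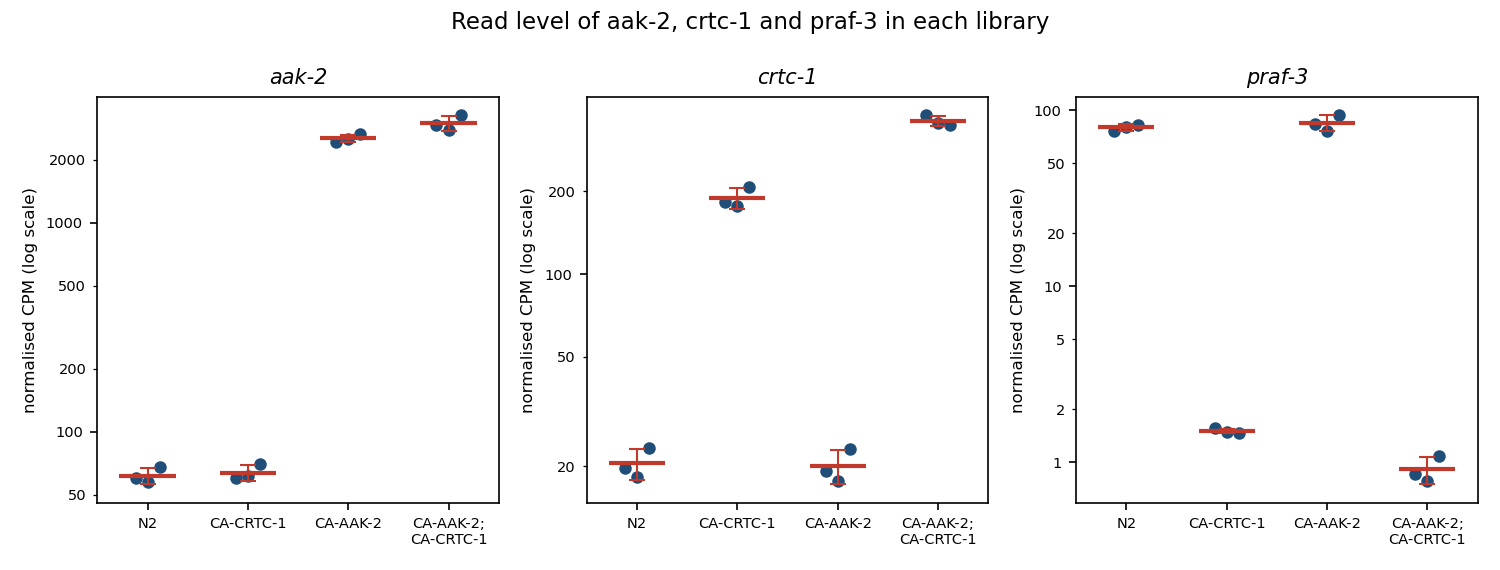
Normalised CPM on a log axis of aak-2, crtc-1 and praf-3 in the 4 strains; points are the 3 libraries of a strain, red lines their mean and red bars 1 SD. praf-3 lies at 79.9 and 84.8 CPM on average in N2 and the CA-AAK-2 strain and at 1.5 and 0.908 CPM in both strains with CA-CRTC-1.

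CA-CRTC-1 against N2 asks what the altered coactivator changes with the worm's own AMPK. Cuticle and moulting genes were among the largest rises of the genes that the naming rule gives. Such genes serve the moult, and whether the strains were at the same point of the L4 stage was not tested. The collagens col-98 (4.39 ± 0.23), col-149 (3.90 ± 0.20) and col-42 (3.8 ± 0.23) rose, as did fbn-1 (4.09 ± 0.32), a fibrillin-like gene of the outer matrix, and dpy-6 (3.90 ± 0.36), a mucin-like cuticle gene. Genes of defence peptides and lysozymes were higher too, among them fipr-2 (2.85 ± 0.17), sysm-1 (2.82 ± 0.19), nlp-27 (2.42 ± 0.17) and lys-5 (1.81 ± 0.15), together with the infection response gene irg-5 (3.82 ± 0.33). The largest fall among the genes past the filter of 5 CPM was that of praf-3, of the prenylated Rab acceptor family, from 79.9 CPM to 1.5 CPM (-5.33 ± 0.11, adjusted p = 2.2e-13).

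Of the 67 measured moulting genes 30 rose and 8 fell, with a median of 0.42. They include grl-21 (3.68 ± 0.25) and grd-3 (3.26 ± 0.17), which are hedgehog-related, and nas-37 (2.55 ± 0.18), a metalloprotease used to shed the old cuticle. Of 124 collagens 29 rose and 22 fell (32 and 22 adjusted over the list alone). Their median was -0.17, their mean was 0.41, and camera placed them below other genes (adjusted p = 0.0203, and 0.795 with an estimated correlation). That call was lost without N2 replicate 2 (0.0738) or CA-CRTC-1 replicate 3 (0.0939). Of 47 antimicrobial genes 16 rose and 2 fell, and of 55 C-type lectins 15 rose and 3 fell (15 and 4), the latter without passing camera (adjusted p = 0.253). Of 27 oogenesis genes 9 rose (10 adjusted over the list alone), with a median of 0.54; examples are meg-1 (1.4 ± 0.21), a gene of germ granules, the eggshell proteoglycan gene cpg-1 (0.96 ± 0.15) and puf-5 (0.87 ± 0.16), which encodes an RNA-binding protein of oocytes. Of 49 neuropeptide genes 6 rose, including nlp-15 (0.77 ± 0.13) and nlp-16 (0.77 ± 0.11). Among the 27 intestinal genes the proteases cpr-4 (1.63 ± 0.14), cpr-5 (1.21 ± 0.11) and asp-6 (0.72 ± 0.09) rose, although the list as a whole did not pass (adjusted p = 0.754). gpdh-1 (-1.33 ± 0.11) and hmit-1.1 (-1.24 ± 0.10), both known to respond to osmotic stress, fell, as did the thioredoxin gene trx-3 (-1.43 ± 0.12). In oxidative phosphorylation, the TCA cycle, glycolysis, gluconeogenesis and 1-carbon and propionate metabolism limma and edgeR each called 0 of 131 genes (18 at an unadjusted p under 0.05), whereas in mitochondrial beta-oxidation the carnitine palmitoyltransferase gene cpt-5 (-1.07 ± 0.18) fell and cpt-6 (0.97 ± 0.15) rose.

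limma called 924 of 10509 genes, 696 higher and 228 lower, and 369 of the rises and 43 of the falls exceeded 2-fold. The median of all genes was 0.07 as deposited and -0.03 when libraries were rescaled by their median ratio, which lowered the share of rises among called genes from 75.3% to 61.7%. camera called 11 lists at an adjusted p of at most 0.05, and 0 of the 11 passed with an estimated correlation (adjusted p = 0.795 or 0.799 with an estimated correlation). The neuropeptide (0.000153), oogenesis (0.000189), antimicrobial (0.000321) and peroxisomal beta-oxidation (0.0203) lists were called with any single library left out. The other 7 were sperm, collagens, UDP-glucuronosyltransferases, ribosomal proteins, moulting, mitochondrial beta-oxidation and autophagy; 5 lists were called without CA-CRTC-1 replicate 3, 7 without N2 replicate 2 and 9 without N2 replicate 1. Moulting had an adjusted p of 0.0405 and 0.0956 without CA-CRTC-1 replicate 3, sperm 0.000189 and 0.0939, and collagens 0.0203 and 0.0939.

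CA-AAK-2 against N2 asks what the active kinase subunit changes by itself. Yolk genes were far lower, and genes of oogenesis were higher. The vitellogenin genes vit-4 (-2.73 ± 0.32), vit-3 (-2.49 ± 0.37) and vit-5 (-2.44 ± 0.38) fell, whereas meg-1 (2.00 ± 0.21), puf-5 (1.54 ± 0.16), cpg-2 (1.19 ± 0.13) and mex-6 (0.88 ± 0.10), a regulator of embryonic polarity, rose. Genes of the pharynx and its muscle were lower: myo-1, a pharyngeal myosin heavy chain, went from 214 ± 17 CPM to 88.1 ± 4.63 CPM (-1.28 ± 0.07, adjusted p = 7.9e-08), and the transporter gene pgp-14 (-2.19 ± 0.15) and the troponin genes tnt-4 (-0.96 ± 0.09) and tnc-2 (-0.73 ± 0.10) fell. Several cuticle genes were higher, as in the CA-CRTC-1 strain, among them dpy-3 (2.49 ± 0.24), bli-1 (2.47 ± 0.24) and noah-2 (2.41 ± 0.25), which encode collagens and a matrix protein needed at the moult.

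All 6 measured vitellogenin genes fell, with a median of -2.15. Of 27 oogenesis genes 23 rose and 0 fell (median 0.99), and the germline list had a median of 0.36 with 2 rises, mcm-3 and pcn-1 of the DNA replication machinery, which did not pass under median-ratio scaling (0.51 and 0.57). Of 11 pharyngeal genes 4 fell (median -0.39), and of 34 muscle genes 3 fell (median -0.25), all of them pharyngeal: myo-1, tnt-4 and tnc-2. The body-wall myosin gene unc-54 stood at -0.24 ± 0.10 (adjusted p = 0.061). The abu and pqn genes, which encode glutamine- and asparagine-rich proteins, held 16 falls and 3 rises among 49 members, led by pqn-2 (-1.91 ± 0.13), abu-1 (-1.72 ± 0.15), abu-11 (-1.61 ± 0.13) and pqn-63 (-1.47 ± 0.10). camera placed the list below other genes (adjusted p = 0.00133, and 0.456 with an estimated correlation) although its median was 0.01. That median was -0.07 under median-ratio scaling. Of the collagens 21 rose and 44 fell (21 and 48), of 36 UDP-glucuronosyltransferase genes 1 rose and 8 fell, among them ugt-64 (-1.18 ± 0.10), and of 62 moulting genes 25 rose and 9 fell (26 and 9), the last without passing camera (adjusted p = 0.434). Intestinal genes moved both ways, with cpr-4 (1.41 ± 0.14) and cpr-5 (0.91 ± 0.11) higher and the filament genes ifb-2 (-0.90 ± 0.08) and ifc-2 (-0.66 ± 0.07) lower. In fatty acid synthesis the elongase genes elo-5 (-0.82 ± 0.10) and elo-6 (-0.77 ± 0.10) fell and acly-2 (0.81 ± 0.08), an ATP citrate lyase gene, rose. gst-4 (-1.07 ± 0.14), a glutathione S-transferase gene, fell, as did tbb-6 (-1.97 ± 0.13), a tubulin gene, and pud-3 (-2.95 ± 0.39). In oxidative phosphorylation, the TCA cycle, glycolysis, gluconeogenesis and 1-carbon and propionate metabolism limma and edgeR each called 3 of 131 genes, 2 of them higher and 1 lower (35 at an unadjusted p under 0.05).

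limma called 1306 of 10368 genes, 850 higher and 456 lower, with 266 and 130 beyond 2-fold. Median-ratio scaling moved the median of all genes from 0.11 to -0.01 and turned the split to 518 higher and 701 lower, so that rises were 65.1% of called genes as deposited and 42.5% after scaling. camera called 11 lists: muscle (adjusted p = 2.1e-10), UDP-glucuronosyltransferases, oogenesis (3.1e-08), pharynx (3.9e-06), collagens, vitellogenins (5.9e-05), germline, peroxisomal beta-oxidation, abu and pqn genes, intestine and proteasome, the last not without CA-AAK-2 replicate 1 (0.0548). The pharynx list also passed with an estimated correlation (adjusted p = 0.0272 with an estimated correlation); for the other 10 the adjusted p with an estimated correlation was 0.456 to 0.569.

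The double strain against N2 asks what both transgenes change together, and this was the comparison with the most changes. Genes of mitochondrial and peroxisomal metabolism were among the falls. acs-2, which encodes an acyl-CoA synthetase that feeds fatty acids into mitochondria, went from 38.6 ± 3.93 CPM in N2 to 2.52 ± 0.672 CPM (-3.71 ± 0.16, adjusted p = 5.8e-10), against 41.9 ± 5.33 CPM in the CA-CRTC-1 strain and 25 ± 4.26 CPM in the CA-AAK-2 strain. icl-1, the enzyme of the glyoxylate shunt, went from 1055 ± 47 to 323 ± 25.6 CPM (-1.71 ± 0.10). The propionate breakdown genes hach-1 (-1.48 ± 0.06), hphd-1 (-1.25 ± 0.06) and ech-6 (-1.23 ± 0.06) fell, and so did cth-1 (-1.91 ± 0.12), which makes cysteine from cystathionine. The rises included genes of oogenesis, neuropeptides, defence and small heat shock proteins.

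Of 26 genes of 1-carbon and propionate metabolism 10 fell (median -0.48), of 29 of mitochondrial beta-oxidation 6 fell (median -0.34), of 27 of peroxisomal beta-oxidation 10 fell and 1 rose (median -0.42), and of 11 that depend on the receptor NHR-49 5 fell (median -0.53). Besides acs-2 and ech-6, the carnitine palmitoyltransferase genes cpt-5 (-2.60 ± 0.18) and cpt-4 (-1.48 ± 0.13), the peroxisomal transporter genes pmp-5 (-1.64 ± 0.09) and pmp-2 (-0.99 ± 0.08), the oxidase gene acox-1.1 (-1.29 ± 0.11) and the thiolase gene daf-22 (-1.1 ± 0.08) fell. Of 52 nuclear genes of oxidative phosphorylation 6 fell (median -0.27), among them gas-1 (-0.72 ± 0.06), a subunit of complex I, and asg-2 (-0.69 ± 0.06), a subunit of the ATP synthase. The TCA cycle had 2 falls among 24 genes (median -0.16) and gluconeogenesis 3 among 17 (median -0.35), which include pyc-1 (-0.67 ± 0.06), a pyruvate carboxylase gene of both lists, and fbp-1 (-0.70 ± 0.07). Ribosomal protein genes had a median of -0.19 with 1 rise and 1 fall among 83. Among genes of oxidative stress and glutathione metabolism 5 rose and 6 fell of 33, and msra-1, which repairs oxidised methionine, went from 502 ± 35.4 to 149.5 ± 13.1 CPM (-1.74 ± 0.09). The metabolic lists above kept negative medians under both other scalings.

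**Figure D2:**
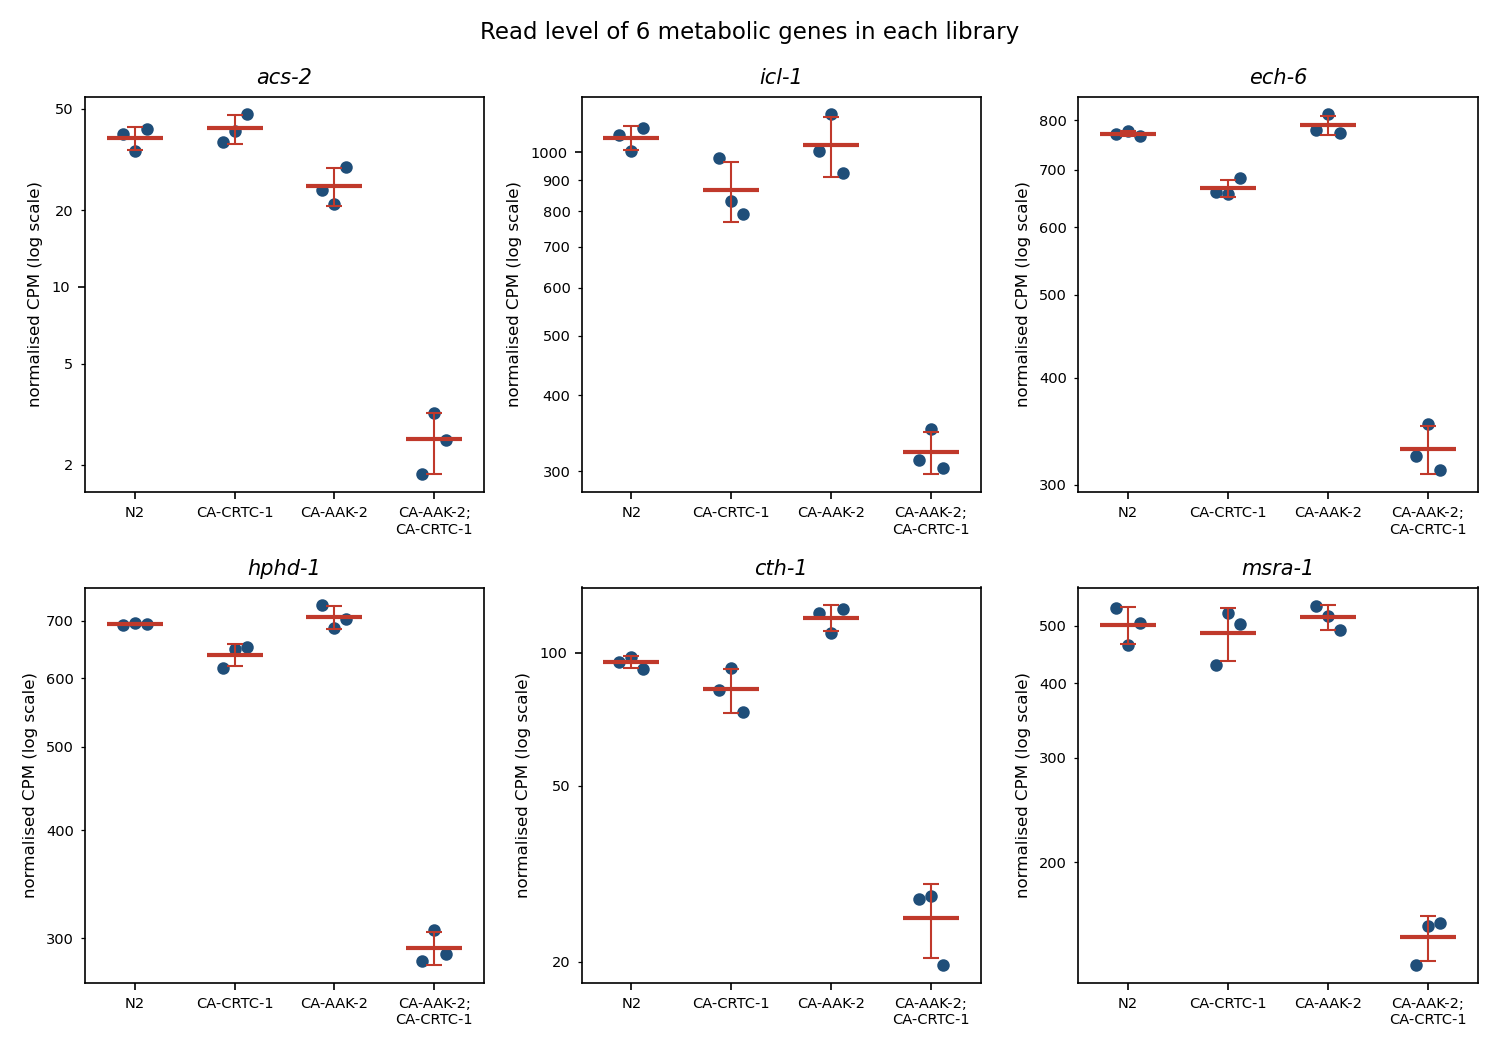
Normalised CPM on log axes of 6 genes named for the double strain, in the 4 strains; points are the 3 libraries of a strain, red lines their mean and red bars 1 SD. acs-2 averages 2.52 CPM and icl-1 323 CPM in the double strain, against 25 and 1026 CPM in the CA-AAK-2 strain.

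On the rising side, 23 of 27 oogenesis genes were higher (median 1.43), led by meg-1 (2.66 ± 0.21) and cpg-1 (2.08 ± 0.15), and 7 of 38 germline genes rose, including mcm-3 (1.02 ± 0.07) and mcm-5 (0.84 ± 0.07). Of 53 neuropeptide genes 26 rose and 0 fell (median 0.63); examples are nlp-15 (1.51 ± 0.13) and nlp-21 (0.88 ± 0.09). Of 47 antimicrobial genes 21 rose and 4 fell (median 0.49), among them sysm-1 (4.48 ± 0.19), fipr-2 (3.25 ± 0.17) and lys-7 (2.80 ± 0.12). Of 12 heat shock genes 5 rose, with hsp-16.41 going from 0.113 ± 0.101 to 26 ± 7.34 CPM (5.41 ± 0.22), although the list did not pass camera (adjusted p = 0.506). lea-1 (2.00 ± 0.14), mtl-1 (3.04 ± 0.20) and sip-1 (2.02 ± 0.13), all linked to stress resistance, rose within the DAF-16 target list, in which 3 genes rose and 3 fell of 12. In monoamine synthesis and signalling 3 of 6 genes rose and 1 fell: tdc-1 (1.28 ± 0.13), which makes tyramine, and cat-4 (0.89 ± 0.13) were higher, and the decarboxylase gene bas-1 (-0.83 ± 0.11) was lower. Of 47 genes of autophagy and the lysosome 9 rose, such as sqst-1 (1.76 ± 0.08), and 7 fell, such as the proton pump genes vha-15 (-0.82 ± 0.06) and vha-8 (-0.74 ± 0.06). Intestinal genes held 10 rises, such as cpr-3 (2.87 ± 0.15), and 6 falls, such as pho-1 (-1.16 ± 0.09), among 27.

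Of 6 vitellogenin genes 4 fell (median -1.42); vit-4 fell by 2.3 on the log2 scale, and vit-3 stood at -3.29 ± 0.37 and at -2.71 without replicate 3 of the double strain. UDP-glucuronosyltransferase genes fell in 18 and rose in 3 of 36 cases (median -0.61), led by ugt-64 (-2.45 ± 0.10), and muscle genes fell in 5 of 34 (median -0.24). Collagens were split evenly, with 33 rises and 33 falls among 124 (33 and 34). The lists of oxidative stress, heat shock, DAF-16 targets, monoamines, autophagy and the lysosome, and the intestine did not pass camera, nor did the remaining lists (adjusted p = 0.0749 to 0.968 over these lists). These held 29 rises and 13 falls among 65 moulting genes (30 and 13), 20 and 8 among 55 C-type lectins, 10 and 7 among 29 cytochrome P450 genes, and 15 and 6 among 52 abu and pqn genes. They held 2 and 1 among 18 glycolysis genes, 3 and 4 among 15 genes of lipolysis and lipid binding, and 1 and 3 among 23 of fatty acid synthesis. There were 4 and 0 among 24 neuronal genes, 1 and 0 among 12 pharyngeal genes, 3 and 1 among 54 sperm genes (3 and 0), 0 and 1 among 8 histones, 0 and 1 in each of the mitochondrial (11 genes) and endoplasmic reticulum (20 genes) stress responses, 0 and 0 among 14 genes of mitochondrial dynamics and 33 of the proteasome, and 6 and 0 among 18 genes of the AMPK and CRTC-1 pathway, transgenes included.

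limma called 2383 of 10594 genes, 1655 higher and 728 lower, with 694 and 257 beyond 2-fold. Median-ratio scaling moved the median of all genes from 0.14 to -0.03 and the called genes to 1071 higher and 1157 lower, so the share of rises went from 69.5% to 48.1%. Replicate 3 of the double strain stood further from the others than any other library stood from its group, and 2471 genes were called without it. camera called 16 lists, and all 16 were called with any single library left out. Oxidative phosphorylation (adjusted p = 1.9e-11; 0.0305 with an estimated correlation), 1-carbon and propionate metabolism (5.4e-10; 0.0156), mitochondrial beta-oxidation (1.4e-08; 0.0258) and NHR-49-dependent genes (0.000673; 0.0450) passed both ways. The other 12, oogenesis, neuropeptides, antimicrobial genes and vitellogenins among them, had adjusted p = 0.0671 to 0.737 with an estimated correlation.

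**Figure D3:**
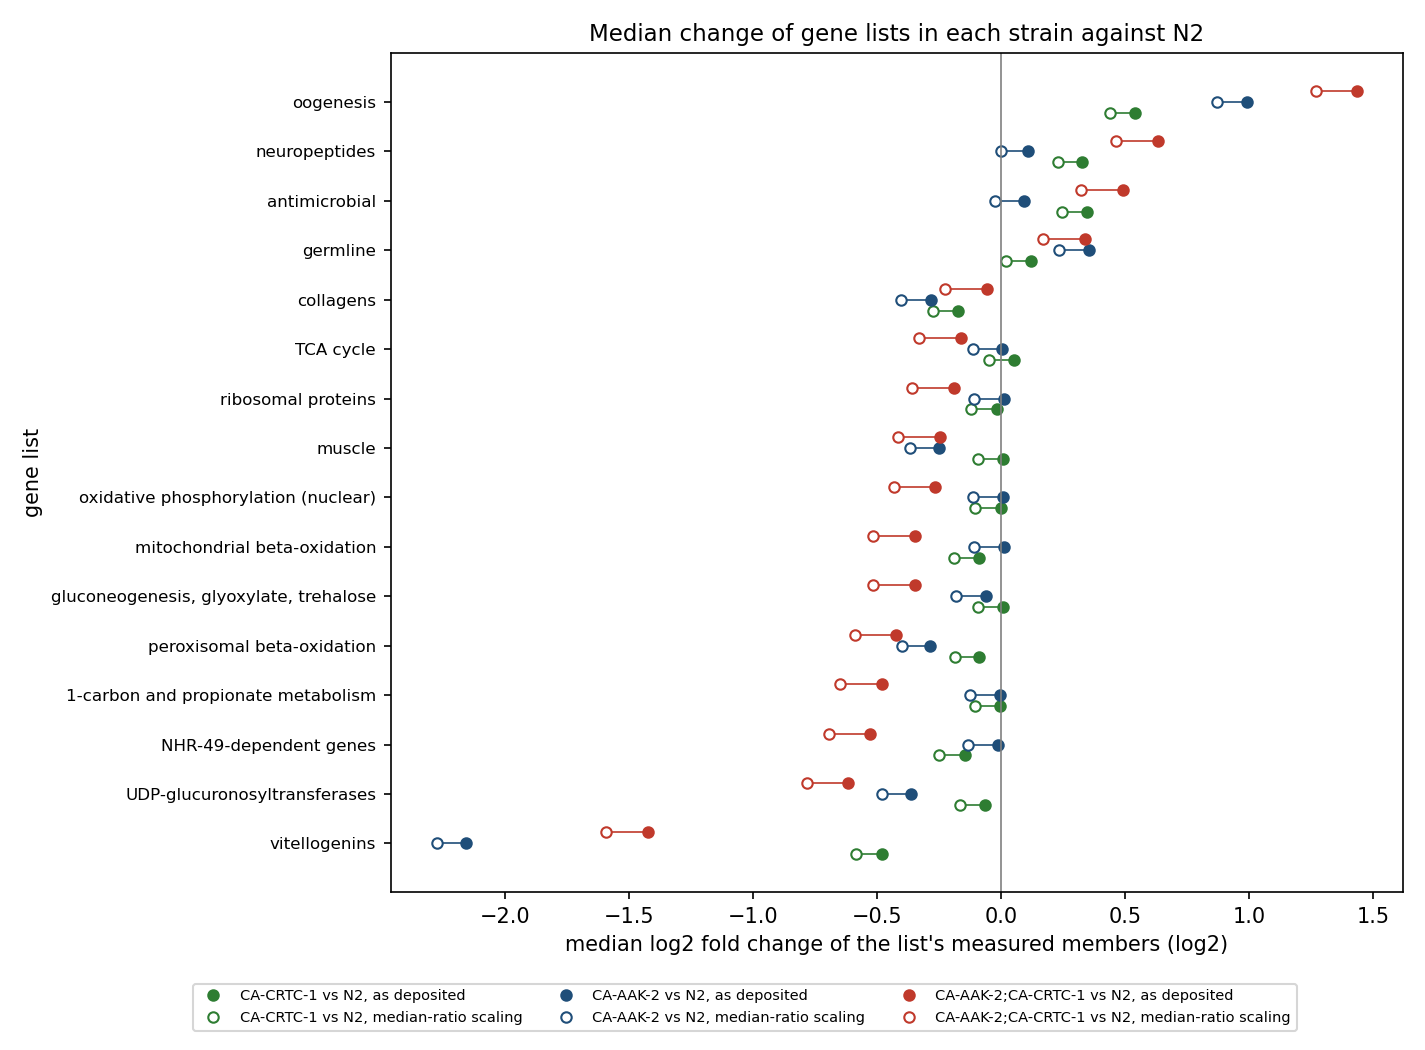
Median log2 fold change against N2 of the 16 gene lists that camera called in the double strain, for each of the 3 transgenic strains; filled points use the deposited values and open points the same values after median-ratio scaling. Metabolic lists lie below 0 in the double strain under both scalings, and 9 of the 48 pairs of medians, all in the single strains, lie on opposite sides of 0.

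The double strain against the CA-AAK-2 strain asks what the addition of CA-CRTC-1 to active AMPK changes. The metabolic falls were present here as well: acs-2 (-3.09 ± 0.16), cth-1 (-2.24 ± 0.12), icl-1 (-1.66 ± 0.10), cpt-4 (-1.65 ± 0.13), hach-1 (-1.46 ± 0.06), hphd-1 (-1.27 ± 0.06) and ech-6 (-1.26 ± 0.06) fell. So did msra-1 (-1.79 ± 0.09) of the oxidative stress list. argk-1, an arginine kinase gene, went from 74.6 ± 5.98 to 16.3 ± 5.17 CPM (-2.2 ± 0.17). praf-3 again lay near zero, at 0.908 CPM against 84.8 CPM (-5.92 ± 0.11). Of the 4 pharyngeal genes that CA-AAK-2 had lowered, 3 were higher with CA-CRTC-1 added, with pgp-14 at 2.64 ± 0.15, tnt-4 at 0.90 ± 0.09 and myo-1 at 0.80 ± 0.07. The fourth, tnc-2, at 0.41 ± 0.10, did not reach the fold threshold. marg-1 (3.04 ± 0.15) rose as well. srlf-34 (4.99 ± 0.21), hsp-16.41 (5.31 ± 0.22) and sysm-1 (3.66 ± 0.19) were higher too.

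Falls numbered 11 of 26 in 1-carbon and propionate metabolism (median -0.43), 5 of 28 in mitochondrial beta-oxidation (median -0.33), 3 of 52 in oxidative phosphorylation (median -0.30), 2 of 24 in the TCA cycle with idh-2 (-0.78 ± 0.10) and pyc-1 (-0.66 ± 0.06), 4 of 16 in gluconeogenesis with pck-1 (-0.78 ± 0.08) and fbp-1 (-0.66 ± 0.07), and 8 of 27 in peroxisomal beta-oxidation beside 1 rise. Rises numbered 6 of 12 in the pharynx list (median 0.50), 18 of 54 among neuropeptides (19 adjusted over the list alone) with nlp-15 (1.49 ± 0.13) and flp-13 (0.88 ± 0.10), 18 beside 2 falls among 47 antimicrobial genes (19 and 2), 15 beside 2 falls among 50 abu and pqn genes with pqn-31 (3.44 ± 0.15) and abu-10 (2.39 ± 0.15), and 8 beside 3 falls among 27 intestinal genes (camera adjusted p = 0.185, not called) with elt-2 (0.75 ± 0.08), the gut GATA factor gene, and ifc-2 (0.75 ± 0.07). Of 27 oogenesis genes 2 rose (1 adjusted over the list alone). tbh-1, which makes octopamine, rose from 9.77 ± 1.4 to 26.5 ± 12.9 CPM (1.29 ± 0.23).

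limma called 1198 of 10607 genes, 813 higher and 385 lower, and 1307 without replicate 3 of the double strain. camera called 17 lists, of which glycolysis (adjusted p = 0.0187) and neurons (0.0154) were not called without that library (0.0974 and 0.0543). Oxidative phosphorylation (1.1e-13; 0.0179 with an estimated correlation), mitochondrial beta-oxidation (2.1e-10; 0.0164), 1-carbon and propionate metabolism (8.5e-10; 0.0164) and pharynx (8.3e-05; 0.0315) also passed with an estimated correlation, and the other 13, which include neuropeptides, antimicrobial genes, ribosomal proteins and proteasome, had adjusted p = 0.0582 to 0.703 with an estimated correlation.

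The double strain against the CA-CRTC-1 strain asks what the addition of CA-AAK-2 changes. The 2 strains also differ in the level of crtc-1 itself (0.94 ± 0.10) and in neighbouring genes on chromosome II. There 2L52.1 stood at 0 CPM in the CA-CRTC-1 strain and 5.27 CPM in the double strain, and osta-1 at 1.17 and 7.67 CPM. Genes of energy metabolism were again among the falls, with acs-2 at -3.83 ± 0.16, acox-1.2 at -2.15 ± 0.20, pmp-5 at -1.51 ± 0.09, icl-1 at -1.42 ± 0.10 and hach-1 at -1.33 ± 0.06. From the oxidative stress list msra-1 (-1.70 ± 0.09) fell. ahcy-1, which clears S-adenosylhomocysteine, went from 3267 ± 142 to 1461 ± 15 CPM (-1.16 ± 0.07). Oogenesis genes rose in 23 of 27 cases (median 0.85), among them cpg-1 (1.13 ± 0.15), cpg-2 (1.02 ± 0.13) and egg-2 (0.98 ± 0.14). The proton pump genes vha-15 (-0.80 ± 0.06), vha-8 (-0.74 ± 0.06) and vha-13 (-0.65 ± 0.06), members of the autophagy and lysosome list, fell. lipl-2 (2.46 ± 0.18), a lipase gene, cyp-37B1 (2.56 ± 0.15), a cytochrome P450 gene, and lys-7 (1.6 ± 0.12) rose.

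Falls numbered 12 of 26 in 1-carbon and propionate metabolism (median -0.55), 6 of 29 in mitochondrial beta-oxidation (median -0.29), 4 of 52 in oxidative phosphorylation (median -0.26), 9 of 27 in peroxisomal beta-oxidation (median -0.30), 3 of 34 in muscle (median -0.30) and 10 beside 1 rise among 47 genes of autophagy and the lysosome (median -0.11), where the falling members named above pump protons (adjusted p = 0.00224; adjusted p = 0.527 with an estimated correlation). UDP-glucuronosyltransferase genes fell in 16 and rose in 1 of 38 cases, with ugt-26 at -1.62 ± 0.08. Of 126 collagens 5 rose and 4 fell (5 and 2), and of 69 moulting genes 2 rose and 6 fell. camera placed both lists below other genes (adjusted p = 0.0391 and 0.00932, and 0.655 for both with an estimated correlation).

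limma called 949 of 10727 genes, 502 higher and 447 lower, and 1191 without replicate 3 of the double strain. Median-ratio scaling lowered the share of rises from 52.9% to 39.8%. camera called 19 lists, 4 of which were lost when 1 library was left out: collagens without CA-CRTC-1 replicate 1 (adjusted p = 0.444) or replicate 1 (0.0597) or 2 (0.0549) of the double strain, moulting without replicate 2 of the double strain (0.379), sperm without CA-CRTC-1 replicate 3 (0.0899) and vitellogenins without replicate 3 of the double strain (0.0627). 1-carbon and propionate metabolism (5.4e-14; 0.00455 with an estimated correlation), oxidative phosphorylation (5.4e-14; 0.0178) and mitochondrial beta-oxidation (2.7e-09; 0.0178) passed with an estimated correlation, and the other 16 had adjusted p = 0.0549 to 0.655 with an estimated correlation.

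The interaction asks whether CA-CRTC-1 made a different change with CA-AAK-2 than without it. Other differences between the CA-CRTC-1 and double strains, such as those in crtc-1 level and at 2L52.1, enter it as well. Of 167 members of 6 metabolic lists 29 had a negative and 1 a positive interaction. The CA-CRTC-1 difference was more negative with CA-AAK-2 for acs-2 (-3.21 ± 0.23), and the interaction was -2.03 ± 0.17 for cth-1, -1.74 ± 0.12 for msra-1, -1.37 ± 0.14 for icl-1, -1.32 ± 0.09 for hach-1, -1.15 ± 0.08 for hphd-1 and -1.05 ± 0.09 for ech-6. Some cuticle and moulting genes that rose with CA-CRTC-1 alone had large negative interactions, such as sym-1 (-3.56 ± 0.39), mltn-1 (-3.52 ± 0.34), dpy-6 (-3.43 ± 0.52), dpy-9 (-3.24 ± 0.33) and noah-2 (-3.14 ± 0.35). Each of these had a higher mean in the CA-AAK-2 strain than in N2 too. For example, noah-2 stood at 19.5, 223, 105 and 144 CPM in N2, CA-CRTC-1, CA-AAK-2 and the double strain (SD 66.7 in the last). The negative term thus holds rises in both single strains that did not add up in the double strain. A difference between strains in time within the L4 stage was not tested for these genes. Some genes that CA-AAK-2 alone lowered had positive interactions, such as pud-4 (3.46 ± 0.49), pgp-14 (1.88 ± 0.21) and abu-10 (1.99 ± 0.21). The interaction subtracts the CA-AAK-2 difference from N2, so genes picked as low there lean towards positive values. acs-2, which CA-AAK-2 lowered too, had the negative interaction given above.

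Of the genes of 1-carbon and propionate metabolism 13 of 26 had a negative interaction and 1 a positive one (median -0.57), and 7 of 29 in mitochondrial beta-oxidation (median -0.31), 4 of 16 in gluconeogenesis (median -0.34), 2 of 24 in the TCA cycle (median -0.20) and 1 of 52 in oxidative phosphorylation (2 adjusted over the list alone; median -0.29) had a negative one. Peroxisomal beta-oxidation, with 4 of 27 negative (median -0.09), did not pass camera (adjusted p = 0.237). Of 66 moulting genes 26 had a negative and 6 a positive interaction (31 and 6 adjusted over the list alone; median -0.59), of 126 collagens 20 a negative and 25 a positive one (22 and 33; median 0.27), and of 52 abu and pqn genes 1 a negative and 17 a positive one (2 and 17; median 0.09). limma called 923 of 10576 genes, 413 positive and 510 negative (506 and 480 under median-ratio scaling, which turns the balance), with counts from 708 (without N2 replicate 2) to 1132 (without replicate 3 of the double strain). camera called 17 lists, of which glycolysis was lost without replicate 3 of the double strain (adjusted p = 0.0734), vitellogenins without its replicate 2 (0.119), CA-CRTC-1 replicate 3 (0.0632) or CA-AAK-2 replicate 3 (0.0698), and sperm without any of 5 libraries (0.0832 to 0.573). 1-carbon and propionate metabolism (3.3e-08; 0.0269 with an estimated correlation), mitochondrial beta-oxidation (3.6e-06; 0.0426) and pharynx (4.7e-05; 0.0426) also passed with an estimated correlation; the other 14 had adjusted p = 0.0634 to 0.836 with an estimated correlation.

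Several genes were set to be reported in every comparison. hsp-60, a mitochondrial chaperone gene, was lower in the double strain than in N2 (-0.84 ± 0.14), while hsp-6, the other marker of the mitochondrial stress response, stood at -0.06 ± 0.07. Against the CA-AAK-2 strain hsp-60 stood at -0.72 ± 0.14, and at -0.55, short of the fold threshold, without replicate 3 of the double strain; against the CA-CRTC-1 strain it stood at -0.61 ± 0.14, and the call ended without that library (-0.44) or without CA-CRTC-1 replicate 1 (-0.56) or 2 (-0.59). hsp-4, a chaperone gene of the endoplasmic reticulum, rose by 0.85 ± 0.13 from the CA-AAK-2 to the double strain; it was 0.53 ± 0.13 above N2 and 0.54 ± 0.13 above the CA-CRTC-1 strain, and passed in both without replicate 2 (0.68 and 0.69) or 3 (0.59 and 0.60) of the double strain. tbh-1 stood at -0.77 ± 0.23 in the CA-AAK-2 strain against N2 (adjusted p = 0.014) and passed at that value when replicate 2 or 3 of the double strain was left out of the fit. It stood 0.52 ± 0.23 above N2 in the double strain and at 0.85, past the threshold, without its replicate 3. fat-5, a desaturase gene, stood at -0.75 ± 0.22 against the CA-AAK-2 strain (adjusted p = 0.018), and passed without double strain replicate 1 (-1.06) or CA-AAK-2 replicate 2 (-0.97), and with replicate number as a block (adjusted p = 0.00734). aco-2, the aconitase gene, stood between -0.07 and 0.10 and unc-54 between -0.24 and 0.14 in the 5 pairwise comparisons. cpt-5 lay under the filter of 5 CPM against both single strains, with -1.66 ± 0.18 and -1.54 ± 0.18 there, and passed when the filter was 1 CPM. sod-3 (1.49 to 2.47 CPM) and octr-1 (0.897 to 2.08 CPM), an octopamine receptor gene, lay under it everywhere, and fat-7 was not analysed here. acs-2 was lower in the CA-AAK-2 strain than in N2 (-0.62 ± 0.16), a call that ended without CA-AAK-2 replicate 2 (-0.51), N2 replicate 3 (-0.57), or replicate 1 of either (-0.60 each).

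Each transgene's effect was compared across both backgrounds, using differences that share no library. Over 10576 genes the CA-CRTC-1 effect with CA-AAK-2 correlated with that without it at r = 0.479 (rho = 0.359), across genes, which are not independent replicates. Both backgrounds called 267 genes higher and 54 lower, where independent lists would share 46.0 and 7.67, while 16 and 9 genes were called in opposite directions. For the CA-AAK-2 effect r was 0.298 (rho = 0.416), with 182 genes higher and 59 lower in both against 32.1 and 18, and 40 and 18 in opposite directions. Leaving out called genes gave r = 0.241 for CA-CRTC-1 over 8872 genes and 0.335 for CA-AAK-2 over 8686 genes.

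Against N2, the CA-CRTC-1 and CA-AAK-2 strains shared 311 rises and 123 falls, where independent lists would share 45.3 and 10.1, and 14 genes were called in opposite directions. noah-2 and cpr-4 were among the shared rises and ugt-64 among the shared falls. The CA-CRTC-1 and double strains shared 549 and 176 (96.3 and 15.7 for independent lists), and the CA-AAK-2 and double strains 633 and 215 (118 and 32.2). In 20 simulations unchanged groups drawn around the N2 means shared their drawn N2 libraries. Shared calls averaged 0 there, which groups without change give in any case, so this says nothing about overlaps of real calls. The simulated correlations were 0.499 to 0.507, against 0.643, 0.790 and 0.669 in the data, but a shared control gives such values however small the noise. Covariances were 0.123, 0.229 and 0.179 in the data against 0.00792 to 0.00806 simulated. The 3 N2 libraries enter every one of these comparisons, and the simulated covariances are the only control for that here.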

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

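The tests of cell share, crtc-1 dose and stage were chosen only after the result was seen; the counts of other splits were planned. The results in this part are those for which the CA-CRTC-1 difference itself differed between the CA-AAK-2 background and the wild-type background, by the interaction term in limma for genes and camera for lists.

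The interaction called 923 genes. Of 100 splits of the 12 samples, 1, the real one, gave as many, and the highest other split gave 77. These splits shuffled the labels of all strains, so each shuffled group mixed strains that differ and held a wider spread. They test whether the strains differ at all, and cannot exclude chance for the interaction itself. For the pairwise comparisons 6 samples allow 10 splits, too few for a share under 0.05; 1 split, the real one, reached the real count in each, with 924, 1306, 2383, 1198 and 949 genes for CA-CRTC-1, CA-AAK-2 and the double strain against N2 and for the double strain against CA-AAK-2 and CA-CRTC-1, and the highest other split gave 0.

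Of 168 members of 6 metabolic lists 35 were called lower and 1 higher in the double strain against N2, and the median was -0.00 with CA-CRTC-1, -0.01 with CA-AAK-2 and -0.32 with both. camera called all 6 lists there, but peroxisomal beta-oxidation, the TCA cycle and gluconeogenesis did not pass with an estimated correlation (adjusted p = 0.189, 0.296 and 0.0671 with an estimated correlation). The pooled medians hide that peroxisomal beta-oxidation already had a median of -0.28 in the CA-AAK-2 strain, against -0.42 in the double strain. camera also called that list in both single strains, and not in the interaction. Mitochondrial beta-oxidation was called in the CA-CRTC-1 strain too. Under median-ratio scaling the medians of the 6 lists were -0.05 to -0.19 with CA-CRTC-1, -0.11 to -0.40 with CA-AAK-2 and -0.33 to -0.65 with both. A lower share of intestinal cells would by itself lower intestinal markers alike, but 10 of 27 were called higher and 6 lower. Among these markers cpr-3 was also called higher in the CA-CRTC-1 strain, and cpr-4 and cpr-5 in both single strains. Intestinal markers may thus change for reasons other than cell share, so these counts cannot exclude a lower share. A crtc-1 effect in proportion to its level would leave no excess, but the fall exceeded that prediction by a median of -0.3018 (SE 0.0209, from resampling the genes). A later stage as read from the oogenesis genes would lower these lists in the CA-AAK-2 strain as well, where the median was -0.0088. Both values rest on the single-strain medians that set this pattern apart and that move with the scaling. They restate the pattern and are no separate evidence against dose or stage. A response that is not proportional to crtc-1 and a stage or condition of another kind stay open as well. An effect of CA-CRTC-1 that needs active AMPK may hold, as may an effect of CA-AAK-2 that needs CA-CRTC-1. The interaction is the same for both and cannot tell them apart, and neither was tested beyond it.

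The list medians of the interaction were -0.57 for 1-carbon and propionate metabolism, -0.31 for mitochondrial beta-oxidation, -0.29 for oxidative phosphorylation, -0.34 for gluconeogenesis, -0.28 for NHR-49-dependent genes, -0.22 for glycolysis, -0.20 for the TCA cycle, -0.24 for the proteasome, -0.17 for ribosomal proteins and -0.25 for autophagy and the lysosome. They were -0.59 for moulting, 0.27 for collagens, 0.0904 for abu and pqn genes, 0.37 for pharynx, 0.18 for neuropeptides, 0.93 for vitellogenins and 0.034 for sperm. Only 1-carbon and propionate metabolism, mitochondrial beta-oxidation and pharynx also passed with an estimated correlation; the other 14 had adjusted p = 0.0634 to 0.836 with an estimated correlation. Without replicate 3 of the double strain the adjusted p of glycolysis was 0.0734. That of vitellogenins was 0.119 without replicate 2 of the double strain, 0.0632 without CA-CRTC-1 replicate 3 and 0.0698 without CA-AAK-2 replicate 3, and that of sperm 0.0832 to 0.573 without any of 5 libraries.

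Metabolic genes with a negative interaction were acs-2 (-3.21), acox-1.2 (-2.18), argk-1 (-2.06), cth-1 (-2.03), icl-1 (-1.37), cpt-4 (-1.33), hach-1 (-1.32), pmp-5 (-1.18), cpt-6 (-1.17), hphd-1 (-1.15), ech-6 (-1.05), idh-2 (-0.91), pck-1 (-0.88), ahcy-1 (-0.71), fbp-1 (-0.67), pyc-1 (-0.62) and asg-2 (-0.59). A negative interaction was also called for msra-1 (-1.74) of the oxidative stress list and for the UDP-glucuronosyltransferase gene ugt-26 (-1.34). The call of pyc-1 ended without N2 replicate 2 (-0.58). That of asg-2 ended without N2 replicate 2 (-0.58) or 3 (-0.57), CA-CRTC-1 replicate 2 (-0.57), replicate 2 of the double strain (-0.56) or CA-AAK-2 replicate 3 (-0.57).

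Cuticle, moulting and protease genes with a negative interaction were sym-1 (-3.56), mltn-1 (-3.52), dpy-6 (-3.43), fbn-1 (-3.36), dpy-9 (-3.24), dpy-3 (-3.17), noah-2 (-3.14), bli-1 (-2.70), col-149 (-2.48), nas-37 (-2.19), cpr-4 (-1.49), grd-3 (-1.3) and cpr-5 (-0.90).

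Genes with a positive interaction were srlf-34 (3.66), pud-4 (3.46), hsp-16.41 (3.44), pud-3 (3.25), lipl-2 (2.41), tbb-6 (2.29), abu-10 (1.99), pgp-14 (1.88), cyp-37B1 (1.85), mtl-1 (1.81), abu-1 (1.68), pqn-2 (1.6), abu-11 (1.53), trx-3 (1.38), pqn-63 (1.26), lea-1 (1.14), crtc-1 (0.97), hmit-1.1 (0.96), ifc-2 (0.89), hsp-4 (0.86), ifb-2 (0.79), tnt-4 (0.78) and elt-2 (0.69). The mean of hsp-16.41 fell under the filter without replicate 1 of the double strain (3.26), and that of mtl-1 without its replicate 3 (1.6). hsp-4 missed the threshold (adjusted p = 0.0114 to 0.0136) without any of the 3 N2 libraries, CA-CRTC-1 replicate 1 or 2, or CA-AAK-2 replicate 2 or 3. tbh-1 (0.99, adjusted p = 0.0461) and rol-6 (-0.42) passed the threshold without replicate 3 of the double strain (1.31 and -0.62).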

How the results depend on the processing

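Leaving out each library for the gene lists was chosen only after the data were seen; the other alternatives were planned. 0 called genes reversed direction under any alternative. Under median-ratio scaling 796 of 924, 973 of 1306, 1799 of 2383, 1079 of 1198, 827 of 949 and 871 of 923 calls kept their direction and call in CA-CRTC-1, CA-AAK-2 and the double strain against N2, the double strain against CA-AAK-2 and against CA-CRTC-1, and the interaction. This scaling divides each library by a factor and so moves every gene of a comparison alike, which shifts the balance of rises and falls.

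An adjusted p of 0.05 without a fold threshold admits smaller changes and called, in the same order, 2799, 5027, 6357, 3748, 4200 and 2191 genes. A filter of 1 CPM tests more genes and called 1436 in CA-CRTC-1 against N2. No filter called 1644 there, 3632 in the double strain against N2 and 1986 in the double strain against CA-AAK-2. Replicate number as a block gave 948, 1333, 2389, 1220, 991 and 1011 genes and changed no list call. Same-numbered samples correlated in all 3 pairs of the CA-AAK-2 and double strains, and there the block changed the call of fat-5 and of no other named gene. In each other comparison of 2 strains at least 1 of the 3 pairs lay under 0.1, and 2 of 12 samples correlated best with their own number in every other strain. tbh-1 in CA-AAK-2 against N2 (-0.77, adjusted p = 0.0139) passed with the block (0.00608) and in the fit of only the 2 strains; the strains of that comparison are not paired. Leaving out 1 library gave 767 to 968, 1113 to 1376, 2279 to 2471, 1085 to 1307, 819 to 1191 and 708 to 1132 genes.

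Called lists with an estimated correlation numbered 0, 1, 4, 4, 3 and 3 in the same order. With a 1 CPM filter CA-CRTC-1 against N2 had 7 called lists, and the cause was not tested. fry called 26 lists in the double strain against N2; it does not compare a list with other genes. Direction differed between camera and fry for collagens in CA-CRTC-1 against N2 (fry adjusted p = 0.740), glycolysis in CA-AAK-2 against N2 (0.0170), and abu and pqn genes (0.000461), cytochrome P450 genes (0.0283) and pharynx (0.00778) in the double strain against N2; the cause was not tested. Leaving out 1 library gave 5 to 11, 10 to 11, 16 to 17, 17 to 18, 17 to 19 and 15 to 20 called lists.

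The correlation of the CA-CRTC-1 effect between backgrounds was 0.46 with a pseudocount of 2 and 0.241 without called genes, and that of the CA-AAK-2 effect was 0.335 without called genes; the cause was not tested. Leaving out 1 library gave 0.434 to 0.504 and 0.246 to 0.339.

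Of the 524 calls of named genes, 490 were kept and 34 lost under median-ratio scaling, 506 and 18 with a pseudocount of 2, 508 and 16 with a constant prior, 510 and 14 with equal totals, and 519 and 5 with edgeR. Depth limits genes near the floor: 743 genes had a mean under 1 CPM and were not tested.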

Other observations

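The tests of germ-cell share, yolk genes, the overlapping gene D2096.9 and the level kept by genes near praf-3 were chosen only after the result was seen, as were 2L52.1 and the families in the last paragraph; the count of neighbours of praf-3 that fell was planned.

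Of 27 oogenesis genes 9, 23 and 23 were called higher than in N2 in CA-CRTC-1, CA-AAK-2 and the double strain, with medians of 0.54, 0.99 and 1.43. camera called the list in all 3, but not with an estimated correlation (adjusted p = 0.795, 0.569 and 0.456 with an estimated correlation). A larger share of germ cells would raise the germline list by about as much. The germline median lay below that of the oogenesis list by at least -0.4189 (SE 0.0518) in each strain, which argues against such a share as the whole cause. The SEs in this paragraph come from resampling the genes of a list, so they leave out the spread among libraries. A later stage at harvest would raise yolk genes as well; their median was -2.15 in the CA-AAK-2 strain and -1.42 in the double strain, but -0.4803 (SE 0.395) in the CA-CRTC-1 strain, within its spread of 0, so stage stays open. Stage may therefore contribute in that strain. In the CA-AAK-2 and double strains the fall of 6 yolk genes cannot exclude it either, since these genes may also change for reasons other than stage. No biological explanation was tested.

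praf-3 fell to 1.5 and 0.908 CPM in both strains with CA-CRTC-1 and not in the others. Of its 4 nearest measured genes, 0 fell at least 2-fold in both strains, while D2096.11 did so in 1 of them (-1.12 against N2, -0.75 in the double strain against CA-AAK-2), so that count does not settle whether a deletion reaches its neighbours. The 3 of these genes with at least 5 CPM in N2 (D2096.7, nap-1 and D2096.11) kept at least 42.82% of their level, which argues against a deletion that removes praf-3 together with the whole of one of them; a change that reaches part of a neighbour, or D2096.9 at 1.66 CPM in N2, stays open. D2096.9, whose annotation overlaps its end, gained -0.2225% of the praf-3 loss, which argues against reads counted for the wrong gene. A change at the locus that came with the CA-CRTC-1 strain could be a candidate source, and the reads do not show where the transgene lies.

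2L52.1 (WBGene00007063), at 1848 to 5514 on chromosome II, had 0 reads over the 3 CA-CRTC-1 libraries and 5.86, 5.84 and 5.27 CPM in N2, CA-AAK-2 and the double strain. With a floor of 3 reads over the group (0.0215 CPM) it was at least 273-fold lower in the CA-CRTC-1 strain than in N2. Its 4 nearest measured genes stood at -2.22 ± 0.16 (osta-1), 1.75 ± 0.19 (best-4), 1.74 ± 0.17 (best-3) and 0.61 ± 0.12 (gmeb-1) in the CA-CRTC-1 strain against N2 and between -0.12 and 0.48 in the double strain against CA-AAK-2, so the difference is not limited to 2L52.1; no explanation was tested.

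Gene families by name prefix were also tested with camera, 134 to 137 of them in the comparisons of the double strain. Of 20 genes of the vacuolar proton pump 10 fell in the double strain against CA-CRTC-1, with a median of -0.57 (camera adjusted p = 5.7e-11; 0.338 with an estimated correlation). Genes of the large and small mitochondrial ribosomal subunits had medians of -0.38 and -0.33 in the double strain against CA-AAK-2 (0.556 for both with an estimated correlation), with 0 of 39 and 1 of 28 genes called by limma. Replicate 2 and 3 of the double strain were the least alike of the 12 pairs of replicates, with a chi-square per degree of freedom of 80.0, against 8.60 for the closest pair.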
